A study of Mus musculus with 20 samples.

How the data were processed

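The series followed the mouse preadipocyte line 3T3-L1 through adipocyte differentiation with DNase I hypersensitive site sequencing (DHS-seq) and chromatin immunoprecipitation sequencing (ChIP-seq). Per the labels, post-confluent cells (day 0) were induced with fetal bovine serum, insulin, the glucocorticoid dexamethasone and the phosphodiesterase inhibitor 3-isobutyl-1-methylxanthine, and nuclei or chromatin were collected at various times. DHS-seq covered day 0, 2 hours, 4 hours, day 1, day 2 and day 6. ChIP-seq covered C/EBPbeta (day 0, 2 hours, 4 hours and day 2), C/EBPdelta (day 0 and 4 hours), the glucocorticoid receptor GR, Stat5a and RXR (4 hours), PPARgamma (day 2 and day 6) and RNA polymerase II (RNA Pol II; day 0 and 4 hours).

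The authors deposited 1 peak list for each of 19 samples: 6 DHS-seq and 13 ChIP-seq lists. The remaining sample, an input control, has no list and was not analysed. Each deposited list gives the chromosome, start and end of every peak in base pairs, with no score, height or read count. Peaks lie on mouse genome build mm9, per the submitters' processing notes. The labels and file headers used here name no peak caller, threshold or read depth, so the depth per sample is unknown and the number of peaks stands in its place. Peaks shorter than the shortest peak of the other DHS lists made up 4.25% of the day 1 list and 7.66% of the day 6 list. Positions are printed counted from 1.

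Every group held 1 library. No difference between times was therefore tested against replicate spread, and a peak was called gained or lost only in the sense of being in one list and not in the other. Clopper-Pearson (exact) 95% intervals are given for shares. They cover counting over peaks in these libraries only.

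Peaks were counted as shared when they overlapped by at least 1 bp. Overlapping peaks of the lists compared were merged into union regions, and each region was scored as present or absent in every list. Overlap was compared with 1000 circular shifts of one list along each chromosome, with a one-sided permutation p whose smallest possible value is 0.001. At 4 hours, regions were scored for the number of factors bound among C/EBPbeta, C/EBPdelta, GR, Stat5a and RXR, and regions bound by all 5 are called hotspots, the term of the series title. The share of regions with another peak was tested for a trend over the number of factors by 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 14 lists. Fisher's exact test compared classes of sites within these libraries, and odds ratios carry Wald 95% intervals. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

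On simulated data, a planted share of 20% of C/EBPbeta 4 hours peaks in the DHS day 0 list was returned as 20.4%. Of 200 unrelated lists, 5% gave a p of 0.05 or less, and 100% of 500 planted regions bound by 5 factors were recovered. The unrelated lists were themselves circular shifts, and the planted peaks were placed to overlap. These figures therefore check the calculation, not whether shifts are a fair background for real peaks.

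The comparisons, their alternatives and the rule for named regions were fixed before the data were examined. The rule named the 5 widest hotspots, the 3 widest regions of each gained or lost class, and chromosomes by region density. Alternatives were an overlap of at least 50% of the shorter peak, a gap of up to 500 bp, every peak set to 200 bp, the wider peaks of each list only, lists shortened to equal length by width, and a background of 1000 random draws from the union of all peaks. Width replaced the score in these because the lists have none. Shares in 200 bp around the middle of merged regions, and among regions with C/EBPbeta at 4 hours, were added after the data were examined. The gene annotation at hand was of another build (GRCm38.p6), and no mm9 annotation or genome sequence was used here. Gene lists near gained regions and sequence motifs in peaks were therefore left out, and regions are named by position only.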

Results

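The data were 19 peak lists from 3T3-L1 cells, a mouse line that turns from preadipocyte to adipocyte after hormonal induction, with 1 library per group and no replicates. The lists held 284878 peaks in all. The 6 DHS lists, which mark open chromatin, ran from 9055 peaks at 2 hours to 35389 on day 1. Among the ChIP-seq lists, the shortest was RXR at 4 hours (2076 peaks) and the longest C/EBPbeta at 4 hours (29957 peaks). Median peak width lay between 484 bp (DHS day 6) and 760 bp (PPARgamma day 6).

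**Figure D1:**
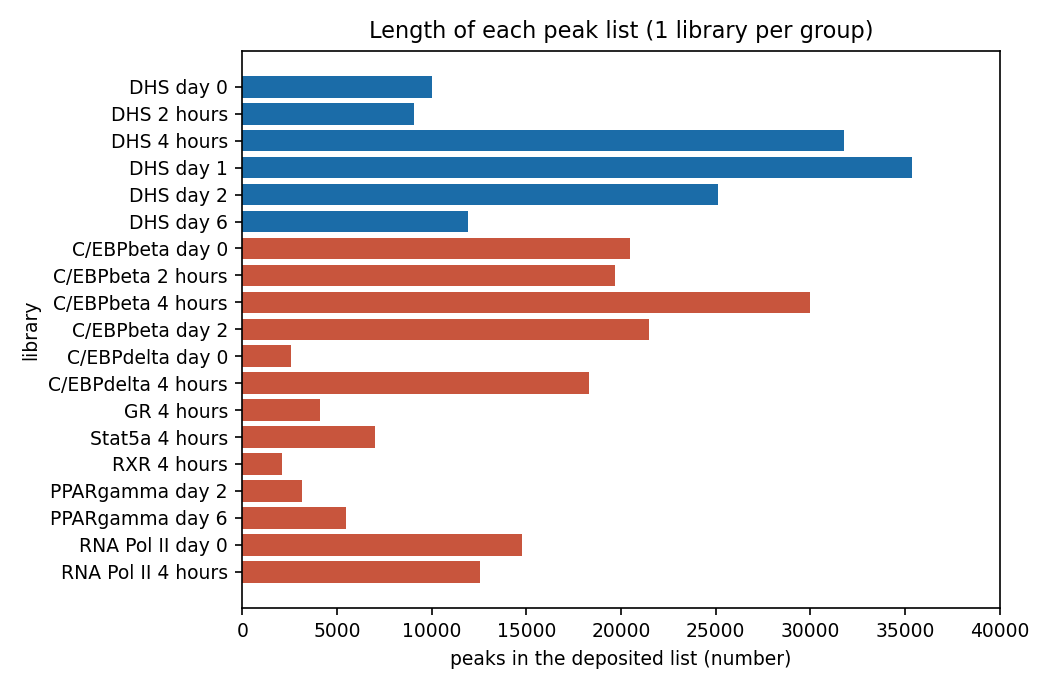
Number of peaks (horizontal axis) in each of the 19 deposited lists, 1 library per bar, DHS-seq in blue and ChIP-seq in red. The DHS lists of 4 hours, day 1 and day 2 (31751, 35389 and 25097 peaks) are longer than those of day 0, 2 hours and day 6 (9989, 9055 and 11936).

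The first comparison asked which chromatin was open before and after induction. Open regions were listed in far greater number at 4 hours (31751 peaks) than on day 0 (9989), and the list was short again on day 6 (11936). Of the day 0 peaks, 93.8% (95% interval 93.3 to 94.2, n = 9989) were also in the 4 hours list, whereas 29.2% of 31751 peaks at 4 hours were in the day 0 list. Among 46760 union regions, 22073 were in the 4 hours list and not in the day 0 list, and 602 were in the day 0 list and not in the 4 hours list (1196 with peaks set to 200 bp; 11223 gained with the wider peaks of each list only). Of the regions gained by 4 hours, 68.3% were still listed on day 1, 41.6% on day 2 and 14.2% (13.8 to 14.7) on day 6. With all 6 lists shortened to 9055 peaks by width, which makes both counts nearly equal by construction, 3844 regions were gained and 3745 lost, 58.2% of day 0 peaks were found at 4 hours, and the share of 4 hours peaks found on day 6 was 53.8% in place of 32.1%. The excess of gained regions, and shares of long lists found in short ones, therefore cannot be separated from list length. Every overlap between DHS lists exceeded all 1000 circular shifts (one-sided permutation p = 0.001, the smallest possible).

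The 2 hours list was compared with those of day 0 and 4 hours. Of the day 0 peaks, 53.7% (52.7 to 54.6, n = 9989) were in the 2 hours list, and 96.3% of the 9055 peaks at 2 hours were in the longer 4 hours list. At equal list length by width, the shares of day 0 peaks found at 2 hours and at 4 hours were close (56.6% and 58.2%). Of the 22073 regions gained by 4 hours, 3332 (15.1%) were already listed at 2 hours. These early regions held a C/EBPbeta 4 hours peak in 81.9% (80.5 to 83.2) and a GR peak in 38.2% (36.6 to 39.9) of cases, against 47.5% and 11.2% for all regions gained by 4 hours. By base pairs, the Jaccard index of day 0 was 46.2% with day 6 and 25.9% with 4 hours, but the lengths the lists cover allow at most 28.7% for the latter, so this order does not rank likeness.

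Regions open throughout and regions gained by 4 hours held different peaks. RNA Pol II of day 0 lay at 65.8% (64.4 to 67.3) of the 4098 regions found in all 6 DHS lists and at 15.1% (14.6 to 15.5) of the 22073 gained regions. Since the former are wider (median 999.5 bp against 602 bp), the shares were also taken in 200 bp around the middle of each region, where they were 59.6% and 13.8%. C/EBPbeta of 4 hours lay at 37.8% of the former and 47.5% of the latter. Gained regions that were still listed on day 6 (n = 3139) held RNA Pol II of day 0 in 45.2% and PPARgamma of day 6 in 17.9% of cases, and those absent on day 6 (n = 18934) in 10.1% and 3.27%. Those still listed are wider (median 732 bp against 584 bp), and PPARgamma of day 6 is set against the DHS list of its own day. Part of both differences may therefore be built in. The 602 regions lost by 4 hours held a C/EBPbeta peak in 29.2% (25.6 to 33.0) on day 0 and in 11.8% (9.33 to 14.6) at 4 hours, and 58.1% of them were listed again on day 1 or later. The widest gained regions were on chromosome 9 at 78320463 to 78326071, chromosome 10 at 96082196 to 96087555 and chromosome 15 at 61814637 to 61819976, each with both RNA Pol II peaks. These widths are of merged regions: the first is 1 day 2 peak of 5609 bp around a 4 hours peak of 591 bp, and the others join 5 and 3 peaks of 4 hours with longer ones of day 2. The widest lost regions were on chromosome 2 at 13306520 to 13307972, chromosome 10 at 37479950 to 37481358 and chromosome 9 at 51201684 to 51203038, each as wide as 1 peak of day 1 or day 2, so being listed again then was fixed by the choice by width.

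The next comparison followed C/EBPbeta, an early adipogenic transcription factor, over 4 times. Of its 20471 day 0 peaks, 72.7% (72.1 to 73.3) were also bound at 4 hours and 5586 were not. Of its 29957 peaks at 4 hours, 15040 were not in the day 0 list. Of the 19703 peaks at 2 hours, 90.1% were in the 4 hours list, and of the 21486 peaks on day 2, 72.1% were. At equal list length by width, which makes both counts nearly equal by construction, gained and lost sites were 8638 and 8623. C/EBPdelta, a related factor, had 2581 peaks on day 0 and 18327 at 4 hours, of which 83.6% overlapped C/EBPbeta; 79.5% of its day 0 peaks were kept at 4 hours (25.6% at equal list length). All of these overlaps exceeded every shift (permutation p = 0.001). The widest C/EBPbeta sites gained by 4 hours were on chromosome 7 at 98719311 to 98721188, chromosome 14 at 100143883 to 100145524 and chromosome 12 at 71159938 to 71161578, and each also held C/EBPdelta, GR, Stat5a and RXR. The widest lost sites were on chromosome 13 at 17237563 to 17239022, chromosome 6 at 94895606 to 94897036 and chromosome 14 at 34611347 to 34612745. C/EBPbeta was listed again on day 2 at the chromosome 13 site, where it was also listed at 2 hours, and at the chromosome 6 site, there together with PPARgamma of day 2 and day 6. At both sites a day 2 peak joins 2 day 0 peaks into 1 wider region, so the choice by width favoured this.

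Whether C/EBPbeta sites were open before induction was examined by overlap with the DHS lists. Of the 29957 C/EBPbeta peaks at 4 hours, 9.90% (9.57 to 10.2) were in the day 0 DHS list and 45.6% (45.0 to 46.1) in the 4 hours DHS list. On day 0, 17305 of 20471 C/EBPbeta peaks (84.5%) lay outside the DHS list of that day, and 37.6% (36.9 to 38.3) of these were in the DHS list at 4 hours. That share was 48.3% of the 12324 sites still bound at 4 hours and 11.1% of the 4981 sites no longer bound (odds ratio 7.51, 6.83 to 8.27, Fisher's exact test across sites). Sites bound at 4 hours were in the day 0 DHS list in 17.3% of cases when C/EBPbeta was already there on day 0 and in 2.60% when it was not (odds ratio 7.82, 7.01 to 8.72). The overlap of C/EBPbeta 4 hours peaks with the day 0 DHS list was 20.2-fold above the shifts (permutation p = 0.001), but 0.873-fold against random draws from the union of all peaks. Of the 9989 widest C/EBPbeta 4 hours peaks, as many as the day 0 DHS list held, 15.1% were in that DHS list. The day 0 and 4 hours DHS lists (9989 and 31751 peaks) were not set to equal length for these shares. The rise from 9.90% to 45.6%, and the 37.6% listed at 4 hours, therefore cannot be separated from DHS list length. The 84.5% of day 0 C/EBPbeta peaks outside the DHS list is limited in the same way. That DHS list (9989 peaks) was shorter than the C/EBPbeta list (20471 peaks), so the share does not show how many sites were closed.

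At 4 hours, the 5 factors shared many sites. Of 35341 regions with at least 1 factor, 18586 held 1 factor, 11219 held 2, 3063 held 3, 1535 held 4 and 938 held all 5. Regions bound by 3 or more numbered 5536 (15.7%). Of the 11219 regions with 2 factors, 9846 held the related factors C/EBPbeta and C/EBPdelta. GR, the receptor of dexamethasone, was with at least 2 of the other factors at 85.2% of its 4071 regions. It was with C/EBPbeta at 91.6%, C/EBPdelta at 81.2%, Stat5a at 53.8% and RXR at 30.6% of them. These shares follow the order of the list lengths (29957, 18327, 6977 and 2076 peaks), so they do not rank the partners of GR. Seen from the other side, GR was at 12.5% of C/EBPbeta, 18.2% of C/EBPdelta, 31.6% of Stat5a and 60.3% of RXR regions. RXR, the partner of several nuclear receptors, was with C/EBPbeta at 92.9% and with all other factors at 45.5% of its 2062 regions, and Stat5a was alone at 30.7% of 6933. None of 1000 shifts gave a region bound by all 5 (permutation p = 0.001), and random draws from the union of all peaks gave 0.806 on average and 5 at most. With the lists shortened to equal length by width, 189 regions were bound by all 5, and with the wider peaks of each list only, 326.

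**Figure D2:**
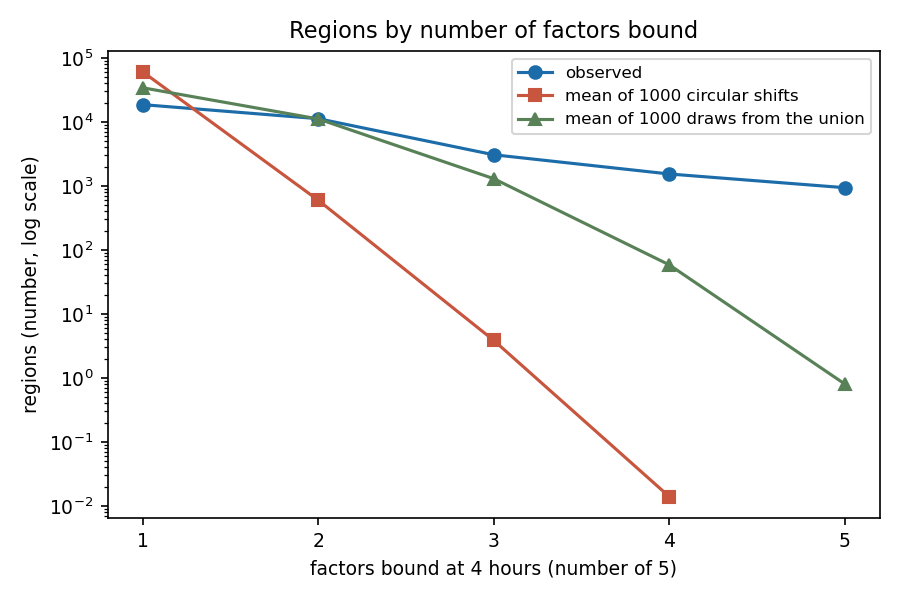
Number of regions (vertical axis, log scale) by the number of factors bound at 4 hours (horizontal axis), as observed and as the mean of 1000 circular shifts or 1000 random draws. All 5 factors shared 938 regions, against a mean of 0.806 by draws; the mean of 0 by shifts is not drawn.

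The 5 widest hotspots are named. The widest lay on chromosome 19 at 5844994 to 5847648 and held a peak in 18 of the 19 lists, including all 6 DHS lists and both RNA Pol II lists. The others were on chromosome 4 at 29388801 to 29391228, chromosome 7 at 91677837 to 91680105, chromosome 19 at 23068099 to 23070300 and chromosome 2 at 65064268 to 65066424. None of these 4 was in the DHS list of day 0 or day 6, and all were in those of 2 hours, 4 hours and day 1. C/EBPbeta was bound on day 0 at each of the 5 except the chromosome 2 region, which held PPARgamma on both day 2 and day 6.

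**Figure D3:**
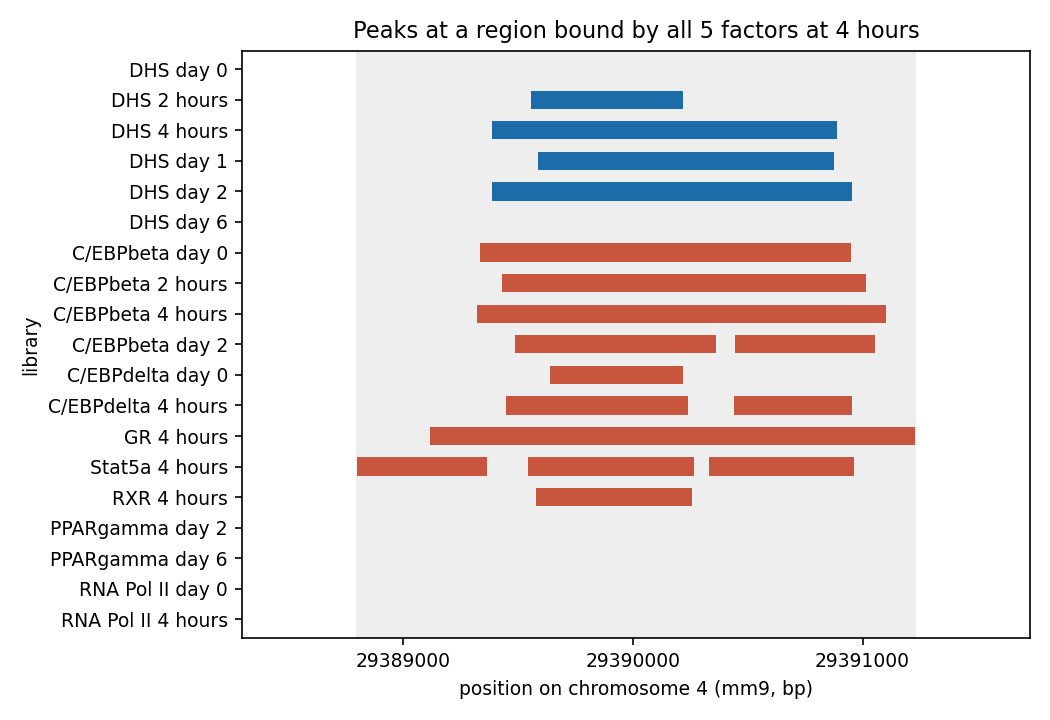
Peaks of each library (vertical axis) along the hotspot on chromosome 4 at 29388801 to 29391228 (horizontal axis, mm9 position in bp), DHS-seq in blue, ChIP-seq in red and the hotspot shaded. C/EBPbeta was listed on day 0, and DHS peaks at 2 hours, 4 hours, day 1 and day 2.

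Hotspots were open more often than regions with fewer factors. The 4 hours DHS list held 84.8% (82.3 to 87.0) of 938 hotspots and 29.1% (28.4 to 29.8) of 18586 regions bound by 1 factor. For the 2 hours DHS list these shares were 65.8% (62.6 to 68.8) and 7.95%, for day 0 19.6% (17.1 to 22.3) and 7.05%, and for day 6 20.3% (17.7 to 23.0) and 7.35%. C/EBPbeta had been bound on day 0 at 78.6% (75.8 to 81.2) of hotspots and 30.1% of regions with 1 factor, or 37.4% of the 13458 of these with C/EBPbeta at 4 hours, which every hotspot holds by definition. Each of these trends over the number of factors passed the permutation test (adjusted p = 2e-05, from the smallest p the permutations can give). The shares for RNA Pol II of day 0 were 5.93%, 7.65%, 4.57%, 3.39% and 3.84% from 1 to 5 factors, not in steady order but lower on balance with more factors (adjusted permutation p = 0.0006), and for RNA Pol II of 4 hours no trend was detected (5.68% and 7.36%, adjusted permutation p = 0.46). Median region width rose with the number of factors as well (520, 639, 761, 861 and 945.5 bp). In 200 bp around the middle of regions with C/EBPbeta, the shares at hotspots and with 1 factor were 83.6% and 32.4% for DHS of 4 hours, 64.9% and 8.28% for 2 hours, 17.9% and 7.16% for day 0, 18.0% and 7.65% for day 6, and 77.2% and 37.2% for C/EBPbeta of day 0 (each trend permutation p = 2e-05). At equal list length by width, here 2076 peaks per list as in the RXR list, hotspots (n = 189) were in the DHS lists of day 0, 2 hours, 4 hours and day 6 in 7.41%, 63.5%, 25.9% and 5.29% of cases and with C/EBPbeta of day 0 in 49.2%, each above the shifts (permutation p = 0.001). This cut took far more from the 4 hours DHS list (31751 peaks) than from the 2 hours list (9055 peaks). These shares therefore do not rank the times by openness.

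**Figure D4:**
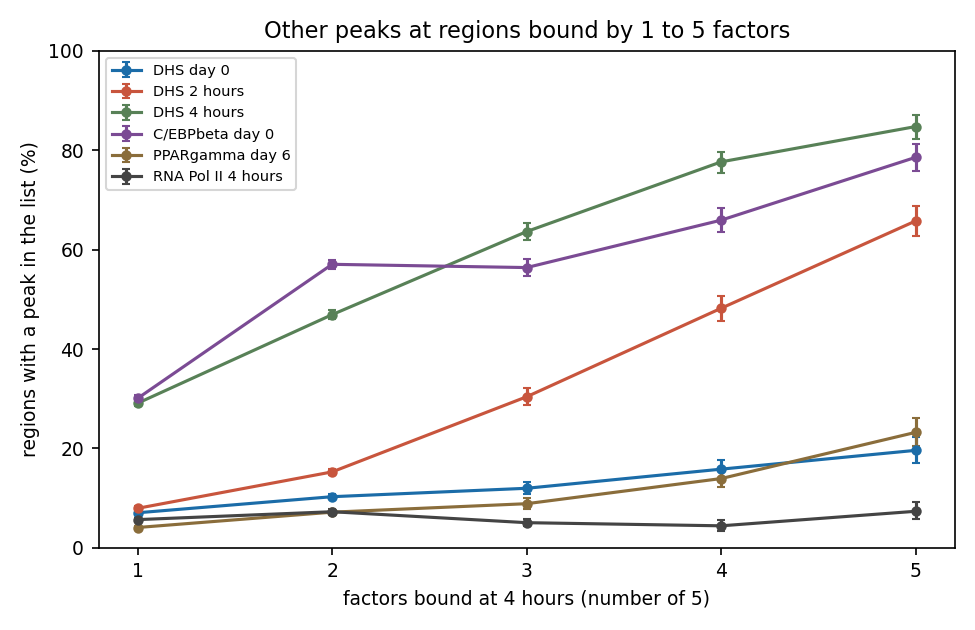
Share of regions with a peak in another list (vertical axis, percent) by the number of factors bound at 4 hours (horizontal axis), with exact 95% intervals. DHS shares at 2 hours run from 7.95% with 1 factor to 65.8% with 5, and RNA Pol II shares at 4 hours from 5.68% to 7.36%.

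**Figure D5:**
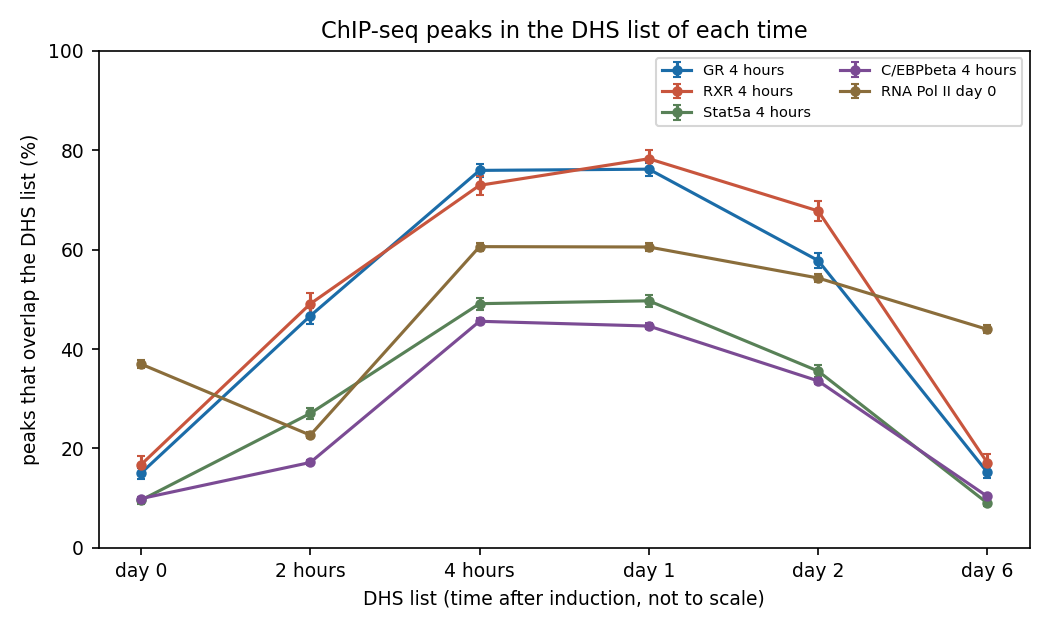
Share of ChIP-seq peaks that overlap each DHS list (vertical axis, percent; bars, exact 95% intervals) over the times of the DHS lists (horizontal axis, not to scale). GR peaks lie at 15.0% on day 0, 46.7% at 2 hours, 75.9% at 4 hours and 15.2% on day 6, and RNA Pol II day 0 peaks at 37.0%, 22.7%, 60.6% and 43.9%.

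PPARgamma, the main regulator of the adipocyte state, was profiled on day 2 and day 6, and its sites were compared with those bound at 4 hours. Of 3168 day 2 peaks, 66.9% (65.2 to 68.5) were kept on day 6, and of 5493 day 6 peaks, 38.5% (37.2 to 39.8) had been there on day 2. Hotspots of 4 hours held 7.64% (6.74 to 8.62) of the day 2 peaks and 4.02% (3.52 to 4.58) of the day 6 peaks, the latter 53.0-fold above the shifts (permutation p = 0.001) and 3.32-fold above random draws from the union of all peaks. Any of the 5 early factors had been at 54.5% and 40.6% of the PPARgamma peaks. Seen from the early sites, PPARgamma of day 6 lay at 23.2% (20.6 to 26.1) of hotspots and 4.09% of regions with 1 factor (adjusted permutation p = 2e-05), or 22.8% and 4.72% in 200 bp around the middle of regions with C/EBPbeta. At equal list length by width, 1.25% of day 6 peaks and 1.97% of day 2 peaks lay in hotspots, and with the wider peaks only 1.57% and 3.72%, each above the shifts (permutation p = 0.001).

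PPARgamma sites kept from day 2 were more often open and bound early than sites seen on day 6 alone. The day 2 DHS list held 80.7% (78.9 to 82.3) of 2105 kept sites, 61.2% (58.2 to 64.2) of 1049 sites of day 2 alone and 42.0% (40.3 to 43.6) of 3377 sites of day 6 alone. C/EBPbeta of 4 hours had been at 54.3%, 49.3% and 29.1% of them, and GR at 17.6%, 19.2% and 5.21%. Kept sites merge peaks of both lists and are wider (median 920 bp) than sites of day 6 alone (716 bp). In 200 bp around the middle of each site, the shares of these 2 classes were 79.0% and 40.5% for the day 2 DHS list, 51.8% and 27.6% for C/EBPbeta and 17.1% and 5.09% for GR (Fisher's exact p of 3.43e-47 or less across sites). The widest sites gained by day 6 were on chromosome 1 at 9537267 to 9539790, chromosome 17 at 21786318 to 21788808 and chromosome 7 at 26174162 to 26176597, each with RNA Pol II of day 0. The widest lost ones were on chromosome 17 at 39983540 to 39985074, chromosome 15 at 61449682 to 61451206 and chromosome 16 at 44174091 to 44175557, each with C/EBPbeta of day 2. The chromosome 17 site stands apart, as it lies inside the widest peak of each of the 6 DHS lists (5962 to 6129 bp).

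RNA Pol II was compared between day 0 and 4 hours as a mark of transcribed regions. Of 14784 day 0 peaks, 55.4% (54.6 to 56.2) were in the 4 hours list, which held 12558 peaks (92.3-fold above the shifts, permutation p = 0.001, and 3.75-fold above random draws from the union of all peaks). In union regions, 7768 were in both lists, 6589 in the day 0 list alone and 4353 in the 4 hours list alone. Regions in both lists merge peaks of both, so that a greater width (median 813 bp, against 384 bp for lost and 385 bp for gained ones) and more overlap with the 4 hours DHS list (83.9%, against 33.7% and 32.9%) are in part built in; in 200 bp around the middle of each region the DHS shares were 79.8%, 32.0% and 29.8%. GR lay at 3.51% (2.99 to 4.11) of gained, 1.09% (0.856 to 1.37) of lost and 0.965% (0.760 to 1.21) of kept regions. The widest gained regions were on chromosome 16 at 15888216 to 15891698, chromosome 14 at 52099698 to 52102997 and chromosome X at 120204223 to 120207194, and the widest lost ones on chromosome 17 at 56239376 to 56242297, chromosome 5 at 58107157 to 58109571 and chromosome 18 at 35024088 to 35026183.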

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

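Of 173 alternative values, 162 kept their direction and their side of the threshold or stayed within the tolerance for counts (1.5 times the reported count). Of the rest, 10 moved beyond it, all of them counts, and 1 reversed. The tolerance was not applied to shares, so a share could change much in size and still be among the 162. Chosen after seeing the data were the alternatives on regions in 14 or more lists, on both RNA Pol II peaks and on absence at 2 hours. So were those on the shortest DHS peaks of day 1 and day 6. The same holds for 200 bp around the middle of merged regions and for regions with C/EBPbeta at 4 hours. None of these moved a count beyond the tolerance or changed the direction or side of the threshold of a share. Each of the 16 shares recomputed stayed above the shifts under each alternative of overlap, width or list length. Peaks set to 200 bp left 1196 DHS regions lost by 4 hours, against 602 (the cause was not tested). Using only the wider peaks of each list gave 11223 gained DHS regions, 8451 gained and 3720 lost C/EBPbeta sites and 326 hotspots, and equal list length by width gave 3844 gained and 3745 lost DHS regions, 8638 gained and 8623 lost C/EBPbeta sites and 189 hotspots. Both alternatives leave fewer peaks in the lists, and equal length makes gained and lost counts nearly equal by construction. Against random draws from the union of all peaks, the share of C/EBPbeta 4 hours peaks in the day 0 DHS list was 0.873-fold, the reverse of the excess over shifts; such draws come from sites already bound or open in some library. The share of hotspots in the 4 hours DHS list ranged from 25.9% (lists shortened to 2076 peaks) to 85.4%, that of day 0 DHS peaks found at 4 hours from 58.2% to 94.4%, and that at 2 hours from 47.7% to 56.6%. Gene lists near gained regions and motifs in peaks, with their alternatives, were not run, for lack of an mm9 annotation and genome. With no scores and no stated depth, absence from a list cannot be separated from a weak signal.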

Other observations

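The tests of RNA Pol II peaks in the 2 hours DHS list, of RNA Pol II at the narrowest day 0 peaks, of the length of the 4 hours list, of library preparation and of RNA Pol II peaks lying on hotspots were chosen only after the result was seen.

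The shares of open regions with other peaks differed by the time they were first listed. Of the 46760 DHS regions, 9763 were first listed on day 1, 4426 on day 2 and 474 on day 6. PPARgamma of day 6 lay at 6.66% (95% interval 6.17 to 7.17), 21.4% (20.2 to 22.6) and 32.9% (28.7 to 37.3) of them, and at 5.36% of regions gained by 4 hours. GR, profiled at 4 hours only, lay at 3.51%, 1.54% and 0 of them, against 11.2% (10.8 to 11.7) of the regions gained by 4 hours; the 0 of 474 allows up to 0.775%. C/EBPbeta of 4 hours lay at 26.9% and 24.0% of regions first listed on day 1 and day 2, against 47.5% of those gained by 4 hours, and C/EBPbeta of day 2 lay at 41.8% (40.4 to 43.3) of regions first listed on day 2. Regions first listed on day 1 or later are by definition absent from the 4 hours DHS list, which held most GR peaks. Their lower shares of GR and of C/EBPbeta of 4 hours are therefore in part built in. Likewise, regions first listed on day 2 or day 6 lie by definition in the DHS list of that day. Their higher shares of ChIP-seq peaks of the same day are in part built in too.

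Hotspots were unevenly spread over the chromosomes. Chromosome 19 held 0.824 per Mb (0.607 to 1.09) and chromosome 6 held 0.717 (0.587 to 0.868), against 0.364 over the genome. Chromosome X held 0.0924 (0.0517 to 0.152) and chromosome 7 held 0.154 (0.0975 to 0.231). Among these chromosomes, C/EBPbeta peaks at 4 hours, which every hotspot holds by definition, were in the same order (19.4, 16.7, 8.99 and 3.59 per Mb on chromosomes 19, 6, 7 and X, against 11.6). So were PPARgamma peaks of day 6 (4.50, 4.15, 1.62 and 0.486, against 2.13) and DHS regions gained by 4 hours (13.2, 10.6, 7.97 and 2.81, against 8.57). RNA Pol II peaks at 4 hours numbered 7.43, 4.54 (interval up to 4.90), 6.49 (6.09 to 6.91) and 3.61 per Mb on the same chromosomes, against 4.87, so chromosome 7 stood above the genome and chromosome 6 was not detectably apart from it. Chromosomes 19, 6, 7 and X are those with the most and fewest hotspots per Mb, and the shared order did not extend to all others. Chromosome 11 held 12.3 gained DHS regions per Mb (11.6 to 12.9) but 0.295 hotspots (0.205 to 0.410). Chromosome 16 held 0.620 hotspots per Mb (0.472 to 0.800) but 8.34 gained DHS regions (7.77 to 8.94). Regions with a peak in all 19 lists numbered 3, on chromosome 6 at 52108098 to 52111582 and 138088429 to 138091118 and on chromosome 19 at 5840838 to 5848914.

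GR peaks of 4 hours were in the DHS list in 15.0% of cases on day 0 and 46.7% at 2 hours. A 2 hours list more sensitive at all sites was argued against, since the share of RNA Pol II day 0 peaks differed by -14.3 percentage points. Those peaks are of day 0, so a greater sensitivity at GR sites only stays open. Widths or list lengths were also argued against. The day 0 and 2 hours lists were alike in both (9989 and 9055 peaks, median 568 and 580 bp). With equal lengths and 200 bp peaks the ratio of shares was 3.81. Among C/EBPbeta 4 hours peaks, the ratio of the 2 hours to the day 0 share was 3.14 with GR and 1.38 without, 2.27 times higher (bootstrap 95% interval 2.09 to 2.44), consistent with early opening at GR-bound sites. Without GR the same ratio was 2.37 with Stat5a, 2.05 with RXR and 1.58 with C/EBPdelta, below 3.14 but above 1.38, so the effect may belong to binding by several factors rather than to GR. A different preparation of the single 2 hours library stays open here too.

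Of the day 0 DHS peaks, 53.7% were in the 2 hours list and 93.8% in the 4 hours list, but with the 6 DHS lists at equal length the share at 4 hours was higher by 1.54 percentage points only (58.2% against 56.6%), so most of the gap may come from the length of the 4 hours list. The share found at 2 hours was 28.0%, 43.5%, 60.5% and 82.3% from the narrowest to the widest of 4 width classes, which may reflect loss of weaker regions, width standing in for strength. Whether that loss was uniform stays open: from the narrowest class to the widest, peaks with RNA Pol II differed from those without by -16.5, -10.1, -3.75 and 2.68 percentage points, but by -7.35 in the narrowest without C/EBPbeta of 2 hours, and over all classes they were found in 54.3% and 52.9% of cases (50.9% and 40.0% without C/EBPbeta). Peaks with C/EBPbeta of 2 hours were found more often than others by 43.8 to 10.7 percentage points across the classes, yet 79.6% of the widest peaks without it were also found, which argues against C/EBPbeta as the whole cause. A different DNase I digestion or library preparation cannot be told apart from the time point, since 2 hours has 1 library.

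RNA Pol II domains (peaks within 10 kb joined) gained by 4 hours had a hotspot within 50 kb in 5.75% of 1982 cases and lost ones in 3.26% of 4141, an odds ratio of 1.81 (1.40 to 2.34, Fisher's exact p = 8.38e-06), which over all domains argues against a shared richness in bound sites alone. It was 2.03 (1.56 to 2.64, Fisher's exact p = 2.68e-07) among domains with C/EBPbeta of 4 hours within 50 kb. Every hotspot holds C/EBPbeta by definition, so this restriction left out only domains without a hotspot within 50 kb. Its outcome therefore rested on how many domains had C/EBPbeta nearby, 44.2% (42.0 to 46.4) of gained and 47.4% (45.9 to 49.0) of lost ones. Gained domains did not have it more often, which argues against the mere presence of a C/EBPbeta peak nearby as the whole cause. The number of C/EBPbeta peaks nearby was not tested. Without domains that overlap a hotspot the odds ratio was 1.36 (1.01 to 1.82, Fisher's exact p = 0.0430), under the bound of 1.5 set for it. Part of the association may therefore come from RNA Pol II peaks on the hotspots themselves (38 gained and 15 lost domains). Other gained domains had a hotspot within 50 kb in 3.91% of cases and other lost ones in 2.91%, and kept domains in 4.25%. A shared richness in bound sites had the same bound of 1.5, so it stays open for domains that do not overlap a hotspot. Shifted hotspots lay near 3.02% of all gained domains on average and 4.39% at most. Shifts without the overlapping domains were not run. Whether hotspots act on nearby transcription was not tested and stays open.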
